A study of Mus musculus with 23 samples.

How the data were processed

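RNA of mouse embryonic fibroblasts, CD8+ T cells and lymphoma cells was hybridised to Affymetrix mouse arrays, with 23 arrays in 6 groups taken from the sample titles. Per the labels, the authors extracted total RNA with Trizol and a column purification and preprocessed the scanned arrays with Robust Multichip Average (RMA), which corrects background, normalises quantiles and summarises probe sets. The RMA software, its version and its probe set definitions are not given in the sources used here. The deposited values were RMA intensity on a linear scale, with 22690 probe sets per array, and were log2-transformed here; the design written beforehand had taken them to be on the log2 scale already. The distributions of the deposited values and the offsets between repeated arrays fell into 3 blocks of 6, 6 and 11 arrays, one per MEF set and one for the T cell arrays, so the arrays were not summarised in a single RMA run. The titles call the samples biological replicates, but whether each came from a separate culture or animal is not stated, and the p-values measure only the spread between these samples. Arrays give no counts, so the number of arrays and the spread between them limit the precision.

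The 64 control probe sets were left out and 22626 were tested. Gene symbols came from the platform's own annotation, in which 20380 probe sets named 1 gene, 691 named several and 1555 named none. A gene table of assembly GRCm38.p6 held 20351 of the gene numbers, changed 0 symbols and was used only for names and gene order, so no positions are printed. Each of 12393 genes was counted through a representative probe set, the one with the highest mean log2 value over all 23 arrays among those naming that gene alone. The values hold no detection calls, and a fold of a gene whose lower group lay in the lowest 25% of the values of its arrays is one of RMA values near the floor. This held on all arrays of a group for 6 of 50 named genes in the Ezh2, 14 of 101 in the Snf5 Ezh2 and 6 of 82 in the lymphoma comparison.

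The 3 control arrays of the second MEF set repeated those of the first. After an offset per probe set was removed, arrays of the same number differed between the sets with an SD of 0.0219 to 0.0241 over 5639 bright probe sets (mean log2 above 9), against 0.137 to 0.152 for different numbers. The offset had a median of 0.07, and it exceeded 0.5 in 0.751% of probe sets. The control hybridisations were therefore counted once: the values of the second set were brought to the scale of the first by the offset of the controls, each control was averaged over both summaries, and 9 distinct MEF arrays entered the fits with 6 residual degrees of freedom. This departed from the design, which had 12 MEF arrays and separate controls for both lines. As a result, both MEF comparisons shared all their controls, the difference between them ignored the error of the offset, and the comparison of both control sets, fitted on 12 arrays, compared RMA runs and not cells.

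Group means were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. The MEF arrays were fitted together and the 11 T cell arrays separately, where 9 residual degrees of freedom remained. The median standard error was 0.0762 in the MEF and 0.229 in the T cell comparison. Ezh2 and Smarcb1 were also compared by exact two-sided permutation of group means. Fixed gene lists, 36 in all with 767 symbols of which 681 were measured, covered chromatin complexes, developmental regulators, cell cycle and growth, stress and interferon responses, T cell states and markers of other cell types. Each list was tested per comparison with limma's camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of the comparison. Other settings of the fit used the preset correlation only. Members were counted with adjustment over all probe sets and over the list alone. Overlaps were tested with Fisher's exact test over genes, and 100 simulations without any effect showed what common controls give by themselves. Named genes were those with the 8 largest rises and the 8 largest falls of each main comparison among called genes whose groups did not overlap, and the 5 largest each way in the other comparisons, without the overlap condition for the difference between both MEF effects. Clone and predicted names were skipped. Ezh2, Smarcb1 and up to 4 called members of each list with the largest change were added, or the member with the smallest p where none was called. The comparisons, lists, named-gene rule and most alternatives were fixed before the data were examined. Genes outside that rule, such as Cd8b1, Lyz2, Eif2s3y and Glo1, were chosen after their values were seen.

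The steps were tested on simulated data with 200 changed among 22626 probe sets. A log2 change of 0.5 was recovered for 88.0% in the Ezh2 comparison, 83.5% in the Snf5 Ezh2 comparison and 87.5% for their difference, and a change of 1 for 99.5% in each. In the lymphoma comparison 0% were recovered at 0.5, 29.5% at 1 and 83.5% at 2. Alternatives were repeated quantile normalisation, median centring, leaving out the 40% dimmest probe sets, a trended and robust prior, array weights, the mean of a gene's probe sets, a 2-fold minimum, fits on fewer or on all arrays, a replicate block and leaving out each array in turn. Alternatives added after the data were seen were the 12 arrays of the design, the Eif2s3y level, fewer wild-type T cell arrays, B cell and myeloid list means, the Gapdh control gap and lists without the deleted genes. Other splits of the arrays were counted for each comparison, all 10 for 3 arrays against 3 and 100 drawn for the lymphomas. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.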

Results

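Gene expression was measured on 23 Affymetrix mouse arrays in 6 groups. The mouse embryonic fibroblasts (MEFs), from E13.5 embryos, were wild type, Ezh2-deficient or deficient in both Snf5 and Ezh2, with 3 arrays per group and a set of 3 wild-type arrays named for each mutant line. The T cell part held 6 arrays of purified CD8+ T cells from wild-type mice and 5 arrays of CD8+ T cells purified from Snf5-deficient lymphomas, all from mice aged 10 to 15 weeks. Ezh2 is the methyltransferase of the Polycomb repressive complex PRC2, and Snf5, encoded by Smarcb1, is a core subunit of the SWI/SNF chromatin remodelling complex. The study was set up to compare the gene programs under both regulators and the program of lymphomas that lack Snf5. Median log2 intensity lay between 7.26 and 7.32 on the MEF arrays and between 8.04 and 8.37 on the T cell arrays, and the precision was limited by the number of arrays and by the spread between them. The median standard error was 0.229 for the T cell arrays and 0.0762 for the MEF arrays. The 3 wild-type arrays of the second MEF set proved to be the same hybridisations as those of the first set, so 9 distinct MEF arrays entered the comparisons.

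The targeted genes were examined first, in every array. Ezh2 read log2 7.95, 7.81 and 7.86 in the wild-type MEFs of the first set and 5.81, 5.65 and 5.63 in the Ezh2-deficient MEFs. In the second set it read 8.02, 8.07 and 8.02 in the wild-type MEFs and 6.65, 6.10 and 6.38 in the Snf5 Ezh2-deficient MEFs. Ezh2 thus fell 4.53-fold in the Ezh2-deficient MEFs (log2 fold change -2.18, SE 0.117, adjusted p = 9.32e-06) and 3.16-fold in the Snf5 Ezh2-deficient MEFs (-1.66, adjusted p = 8.99e-06). Smarcb1 read 9.35, 9.45 and 9.44 in the first wild-type set, 9.22, 9.28 and 9.31 in the Ezh2-deficient MEFs, 9.08, 9.22 and 9.25 in the second wild-type set and 6.77, 6.56 and 6.83 in the Snf5 Ezh2-deficient MEFs. It fell 5.52-fold in the Snf5 Ezh2-deficient MEFs (-2.46, SE 0.076, adjusted p = 1.01e-07), and its difference in the Ezh2-deficient MEFs, -0.14, did not pass (adjusted p = 0.285). Among the T cell arrays Smarcb1 read 11.23, 11.48, 10.38, 10.51, 11.46 and 11.12 in the wild-type cells and 8.30, 8.49, 5.81, 5.64 and 8.67 in the lymphomas, a fall of 12.5-fold (adjusted p = 0.00244; exact two-sided permutation p = 0.00216, the smallest that 5 against 6 arrays can give). Ezh2 was 2.98-fold higher in the lymphomas (log2 13.1 ± 0.199, SD, n = 5, against 11.5 ± 0.828, n = 6; adjusted p = 0.0133; exact permutation p = 0.00433). With 3 arrays against 3 the exact test cannot go below 0.1. A second Smarcb1 probe set fell by 1.88 in the Snf5 Ezh2-deficient MEFs (adjusted p = 8.09e-05) and fell by 1.95 in the lymphomas (adjusted p = 0.0114). Where the probes lie relative to the deleted exons is not given in the sources used here, and a probe outside the deleted part would check nothing.

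**Figure D1:**
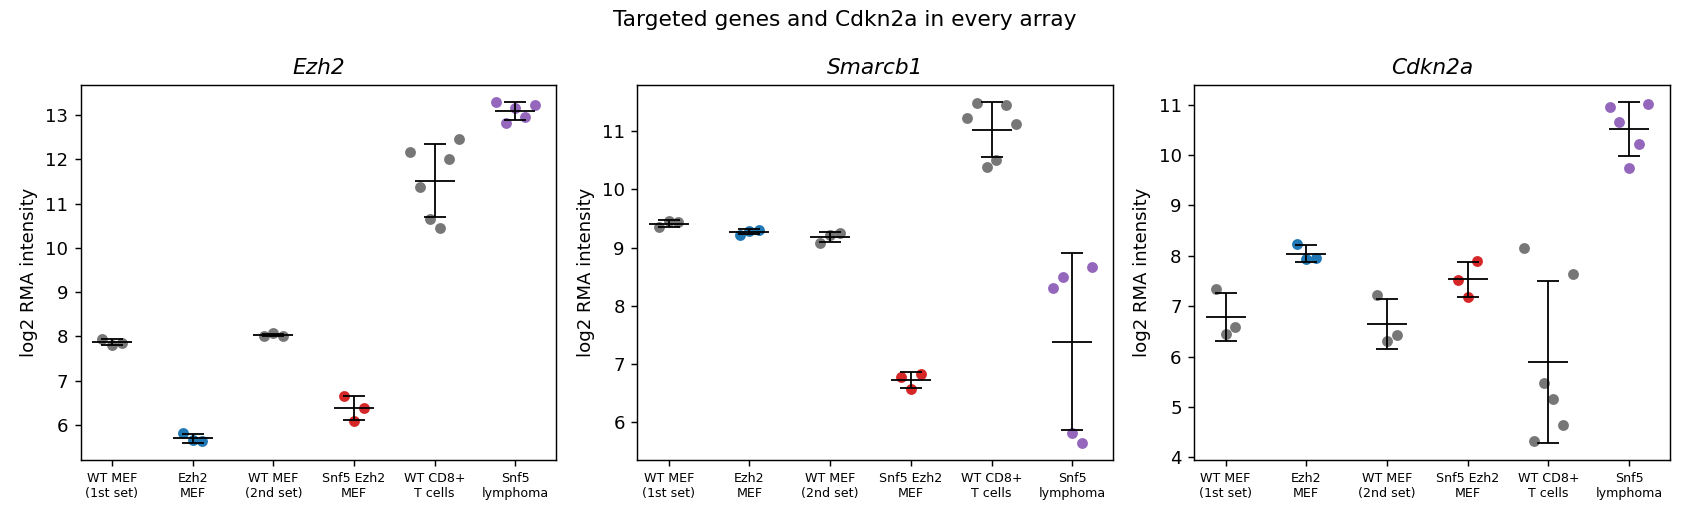
Log2 RMA intensity of Ezh2, Smarcb1 and Cdkn2a in each array of the 6 groups, with a bar for the mean and its SD; values are as deposited, so the second wild-type set and the Snf5 Ezh2-deficient MEFs are on the scale of their own RMA run. Smarcb1 lay between 6.56 and 6.83 in the Snf5 Ezh2-deficient MEFs and between 5.64 and 8.67 in the lymphomas.

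The comparison of Ezh2-deficient with wild-type MEFs asked which genes change when the PRC2 methyltransferase is lost. Of 47 measured proliferation genes, 28 fell, 0 rose and 19 did not pass. Cdkn2a, which encodes inhibitors of the cell cycle and is a known target of Polycomb repression, rose 2.39-fold, from log2 6.79 ± 0.488 to 8.04 ± 0.159 (SD, n = 3 each; SE of the change 0.23; adjusted p = 0.0223). Olr1, a scavenger receptor for oxidised lipoprotein, had the largest rise of the named genes, 3.89-fold (6.98 ± 0.603 against 5.02 ± 0.072; adjusted p = 0.0119). Wdfy1 fell 4.40-fold (log2 fold change -2.14, SE 0.082; adjusted p = 1.29e-06), and Map2, a microtubule protein of neurons, fell 3.31-fold (-1.73, SE 0.215; adjusted p = 0.00478). The lower group of Olr1 and of Map2 lay in the lowest 25% of the values on all 3 of its arrays. These folds are those of RMA values near the floor, as are those of Efcab7 and En1 below. In all, 432 of 12393 genes changed, 126 higher and 306 lower, and 20 of them changed at least 2-fold, 8 higher and 12 lower.

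The other large rises in the Ezh2-deficient MEFs were those of the haem-binding protein gene Hebp1 (log2 fold change 1.5), the non-coding RNA host gene Snhg6 (1.42), the sulphate donor synthase gene Papss2 (1.11), Pop4 (1.08), Fhdc1 (1.07) and Nrep (1.07). The other large falls were those of Angptl7 (-1.51), the calcification inhibitor gene Mgp (-1.48), the chemokine gene Cxcl1 (-1.40), the lipid phosphatase gene Mtm1 (-1.28) and Efcab7 (-1.28). The largest changes were named only among genes whose groups did not overlap. All 432 called genes met that condition, as did 33.7% of all genes, where chance gives 10%. The named proliferation genes were Tk1, thymidine kinase (-0.81, SE 0.137), the replicative helicase subunit gene Mcm5 (-0.76), the mitotic kinesin gene Kif20a (-0.715) and Mki67, a marker of cycling cells (-0.685, SE 0.131). Among Hox genes 0 of 31 rose and 5 fell, including Hoxd13 (-0.805), Hoxa9 (-0.70), Hoxa10 (-0.48) and Hoxd11 (-0.415). The keratin gene Krt7 fell by 1.00. Of 7 CDK inhibitor genes, Cdkn2a rose and Cdkn1b fell (-0.41). Within PRC2, 2 of 11 members fell, Ezh2 itself and the histone-binding subunit gene Rbbp4 (-0.23). Of 13 PRC1 genes Bmi1 rose (0.30), and of 22 SWI/SNF genes 0 passed.

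As a list, proliferation genes had a median log2 change of -0.465 (adjusted p = 7.48e-27 by camera; adjusted p = 0.336 with an estimated correlation), and adjusted over the list alone 42 fell. The list mean per array was 8.09, 8.32 and 8.21 in the wild-type MEFs and 7.68, 7.72 and 7.85 in the Ezh2-deficient MEFs. Sex-linked genes differed inside the Ezh2-deficient group: Eif2s3y, a Y-linked gene, read 8.24, 3.65 and 4.00 there against 8.11 to 8.25 in the wild-type MEFs, while Xist, made from the inactive X chromosome, read 6.45, 9.56 and 9.52. Camera also passed 10 further lists, each with few or no members that passed on their own. It placed p53 target genes (0 of 25 passed, 7 higher adjusted over the list alone; median 0.14, adjusted p = 0.00241), imprinted genes (1 of 23 higher; 0.16, adjusted p = 0.00668), erythroid markers (0 of 12, 3 higher adjusted over the list alone; 0.15, adjusted p = 0.00735), actin contractile genes (0 of 19; 0.11, adjusted p = 0.0187) and developmental transcription factors other than Hox (2 of 95 higher, Pax3 at 0.51 and En1 at 0.355, and 0 adjusted over the list alone; median 0.07, adjusted p = 0.0187) on the higher side. Interferon-stimulated genes were also placed higher (median 0.14, adjusted p = 0.0209), although the 1 member of 30 that passed, Ifit2, fell by 0.59. Ribosome biogenesis genes (0 of 23; -0.12, adjusted p = 0.00241), glycolysis genes (1 of 15 lower, Tpi1 at -0.32, and 5 adjusted over the list alone; median -0.15, adjusted p = 0.00255), PRC2 genes (4 of 11 lower adjusted over the list alone; -0.135, adjusted p = 0.0027) and SWI/SNF genes (-0.09, adjusted p = 0.0301) were placed lower. The PRC2 list holds the deleted gene itself; over its other 10 members the median was -0.125 (adjusted p = 0.0292; adjusted p = 0.336 with an estimated correlation). With an estimated correlation 0 of these 10 calls held, at adjusted p = 0.282 to adjusted p = 0.748. The other 15 lists did not pass camera (adjusted p = 0.0656 to adjusted p = 0.976), Hox genes among them (median -0.003, adjusted p = 0.343; 1 higher and 5 lower adjusted over the list alone), and the macrophage list had a median below 0 with a test on the higher side.

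The size of this comparison rested on single arrays. The 432 genes became 279 without wild-type array 1, 87 without wild-type array 2, 125 without wild-type array 3, 110 without Ezh2-deficient array 1 and 240 without Ezh2-deficient array 3, and 443 without Ezh2-deficient array 2. The 28 proliferation genes became 26, 5 and 9 without wild-type arrays 1, 2 and 3 and 8, 20 and 25 without Ezh2-deficient arrays 1, 2 and 3, and camera passed the list each time. With the Eif2s3y level as a covariate, a setting chosen after the values were seen, 73 genes were called, among them 4 proliferation genes, and Cdkn2a was not (adjusted p = 0.082). The proliferation list kept its size and its camera call in that setting (median -0.52, adjusted p = 5.05e-27). The erythroid (adjusted p = 0.0549), interferon (adjusted p = 0.277) and SWI/SNF lists (adjusted p = 0.174) lost theirs, and the endothelial list gained one (0.112, adjusted p = 0.0494). The call of Cdkn2a ended without wild-type array 2 (adjusted p = 0.0898), wild-type array 3 or Ezh2-deficient array 1 (adjusted p = 0.0774 for each). Those of Tk1, Mcm5, Kif20a and Mki67 ended without any of the same 3 arrays (adjusted p = 0.0599 to adjusted p = 0.0953). Hoxa9 was not called without Ezh2-deficient array 1 (adjusted p = 0.0626), and Hoxd11 was not called without that array (adjusted p = 0.0633) or wild-type array 3 (adjusted p = 0.0712). Angptl7 and Ifit2 were not called without wild-type array 2, wild-type array 3 or Ezh2-deficient array 1 (adjusted p = 0.059 to adjusted p = 0.0896). Cxcl1, Hoxa10, Pax3, Cdkn1b and Tpi1 lost their calls without any array other than Ezh2-deficient array 2, Nrep without any other than Ezh2-deficient array 3, and Bmi1, Rbbp4 and En1 without any of the 6 (adjusted p = 0.0549 to adjusted p = 0.174). The 13 called genes of the named set that kept their call without each array included Olr1, Hebp1, Papss2, Wdfy1, Map2, Mgp, Hoxd13 and Krt7. The 1 imprinted gene and the 2 developmental transcription factors called higher became 3 and 5 without Ezh2-deficient array 2, and 0 of each without wild-type array 2 or 3 or Ezh2-deficient array 1 or 3. Of the lists, interferon-stimulated genes were not called without wild-type array 1 (adjusted p = 0.0512), wild-type array 3 (adjusted p = 0.0526) or Ezh2-deficient array 2 (adjusted p = 0.595). Actin contractile genes lost the call without wild-type array 2 (adjusted p = 0.188) and Ezh2-deficient arrays 1 (adjusted p = 0.145) and 2 (adjusted p = 0.111). SWI/SNF genes lost it without wild-type array 1 (adjusted p = 0.0716) and Ezh2-deficient array 3 (adjusted p = 0.07), and developmental transcription factors without wild-type array 1 (adjusted p = 0.0696) and Ezh2-deficient array 1 (adjusted p = 0.105).

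The comparison of Snf5 Ezh2-deficient with wild-type MEFs asked what combined loss of both regulators changes. Of 30 measured interferon-stimulated genes 25 rose, 1 fell and 4 did not pass. Ifit1, an interferon-induced binder of viral RNA, had the largest rise of the named genes, 19.7-fold, from log2 5.86 ± 0.133 to 10.2 ± 0.823 (SD, n = 3 each; adjusted p = 0.000186), and Cxcl10, an interferon-induced chemokine, rose 12.9-fold (adjusted p = 1.72e-06). Penk, the precursor of enkephalin peptides, rose 18.2-fold (adjusted p = 1.99e-05), the angiotensin receptor gene Agtr2 rose 12.6-fold (adjusted p = 0.000113), and Sfrp2, a secreted inhibitor of Wnt signalling, rose 12.1-fold (adjusted p = 1.91e-05). Glycolysis genes were lower: 11 of 15 fell, 1 rose and 3 did not pass. In all, 3410 of 12393 genes changed, 1632 higher and 1778 lower, and 316 changed at least 2-fold, 176 higher and 140 lower.

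Further large rises were those of the matrix protein genes Abi3bp (log2 fold change 3.53, SE 0.233) and Fndc1 (2.92) and of the cysteine dioxygenase gene Cdo1 (3.11). The large falls, besides Smarcb1, were those of Tmem87a (-2.82), the cGMP-dependent kinase gene Prkg2 (-2.74), Wdfy1 (-2.47), the protease inhibitor gene Tfpi2 (-2.43), Anxa8 (-2.38), Tmem176b (-2.19) and the water channel gene Aqp1 (-2.09), with adjusted p from 1.53e-07 to 0.000124. The lower group of Abi3bp, Tfpi2, Oasl2, Peg10, Nefl, Nefm, Fabp7 and Tnnt2 lay in the lowest 25% of the values on all 3 of its arrays, so their changes are those of values near the floor. Agtr2 did so on 2 of 3 wild-type arrays and Fndc1 on 1 of 3. Of the 3410 called genes, 3384 had all 3 arrays of one group above all 3 of the other, as had 43.9% of all genes, where chance gives 10%. Other members of the interferon list were Usp18 (2.66) and Oasl2 (2.52). Of 23 imprinted genes 10 rose and 4 fell, with Mest at 2.88 (adjusted p = 1.7e-06), Dlk1 at 2.72, Nnat at 2.30 and Peg10 at 1.48. Of 25 p53 target genes 17 rose and 2 fell, with the death receptor gene Fas at 1.875, the peptide transporter gene Tap1 at 1.59, Pmaip1 at 1.43 and Trp53inp1 at 1.01. Whether the rise of the p53 list is separate from that of the interferon list was not tested. Of 7 CDK inhibitor genes 4 rose, among them Cdkn2c (1.73) and Cdkn2a (0.88, adjusted p = 0.0175), and 2 fell, with Cdkn1c at -1.11. The lactate exporter gene Slc16a3 (-1.26) and the hexokinase genes Hk2 (-0.62) and Hk1 (-0.59) fell, as did Nop56 (-0.77), a ribosomal RNA processing gene. Of 47 proliferation genes 4 rose and 3 fell.

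Camera placed the interferon list higher (median 1.16, adjusted p = 9.58e-13; 26 higher and 1 lower adjusted over the list alone), as it did p53 target genes (0.335, adjusted p = 6.53e-08; 17 and 2 adjusted over the list alone) and imprinted genes (median 0.10, mean 0.51, adjusted p = 0.0216; 11 and 5 adjusted over the list alone). It placed glycolysis genes (-0.42, adjusted p = 7.52e-05; 1 and 11 adjusted over the list alone), ribosome biogenesis genes (1 higher and 10 lower of 23; -0.21, adjusted p = 0.000115; 1 and 14 adjusted over the list alone) and actin contractile genes (2 higher and 8 lower of 19; -0.09, adjusted p = 0.0378; 2 and 9 adjusted over the list alone) lower. With an estimated correlation 0 of these 6 calls held: adjusted p = 0.475 for p53 target and glycolysis genes, adjusted p = 0.607 for interferon, ribosome biogenesis and imprinted genes and adjusted p = 0.76 for actin contractile genes. The interferon list mean was 6.58 to 6.63 in the wild-type MEFs and 7.48, 7.86 and 8.23 in the Snf5 Ezh2-deficient MEFs, against 6.69, 7.09 and 6.62 in the Ezh2-deficient MEFs. Macrophage and myeloid markers had a median change of 0.06, with 0 of 19 past the test. The actin list was not called without wild-type array 1 (adjusted p = 0.103), wild-type array 3 (adjusted p = 0.0576) or Snf5 Ezh2-deficient array 2 (adjusted p = 0.0924), and Cdkn2a was not called without wild-type array 2 (adjusted p = 0.0682), wild-type array 3 (adjusted p = 0.0701) or Snf5 Ezh2-deficient array 3 (adjusted p = 0.0653).

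The other 20 lists did not pass camera in this comparison (adjusted p = 0.0774 to adjusted p = 0.986), and several held large changes in both directions. Developmental transcription factors had 18 higher and 2 lower of 95, with the somite factor genes Meox1 (1.14) and Pax1 (0.99) higher. Tbx2 was also higher and Zic1 lower. Their calls ended without any of 2 and of 5 of the 6 arrays left out in turn (adjusted p = 0.0565 to adjusted p = 0.109). Extracellular matrix genes had 5 higher, such as Col11a1 (1.51) and Fbln1 (1.04), and 10 lower, such as Fbln2 (-1.02) and Col5a1 (-0.91). Hox genes had 2 higher, with Hoxc8 at 0.48, and 6 lower, such as Hoxa9 (-0.79), Hoxa10 (-0.58) and Hoxb2 (-0.49). PRC1 genes had 5 higher and 2 lower of 13, with the ubiquitin ligase gene Rnf2 at 1.18 (adjusted p = 6.52e-06), Bmi1 at 0.67 and Cbx6 at 0.39. Among Hedgehog pathway genes the coreceptor gene Gas1 (2.45) and the receptor gene Ptch1 (0.395) rose, and among Wnt target genes Apcdd1 (1.43) rose and Ccn4 (-1.34) fell. Chondrocyte markers had 3 higher, Matn4 (1.625), Col2a1 (1.54) and Matn3 (0.61), and skeletal muscle markers had 4 lower, with Acta1 at -1.53 and Tnnt2 at -1.22. Of those 4, Chrna1 lost its call without any of 4 of the 6 arrays (adjusted p = 0.0685 to adjusted p = 0.128). Tnnc1 lost it without any of the 6 (adjusted p = 0.0646 to adjusted p = 0.141). Neural markers had 5 higher, with Nefl at 1.31 and Nefm at 1.145, and 3 lower, with Fabp7 at -1.425 and Map2 at -1.34. Median, mean and test differed in sign for the PRC2, SWI/SNF, extracellular matrix, neural and erythroid lists.

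**Figure D2:**
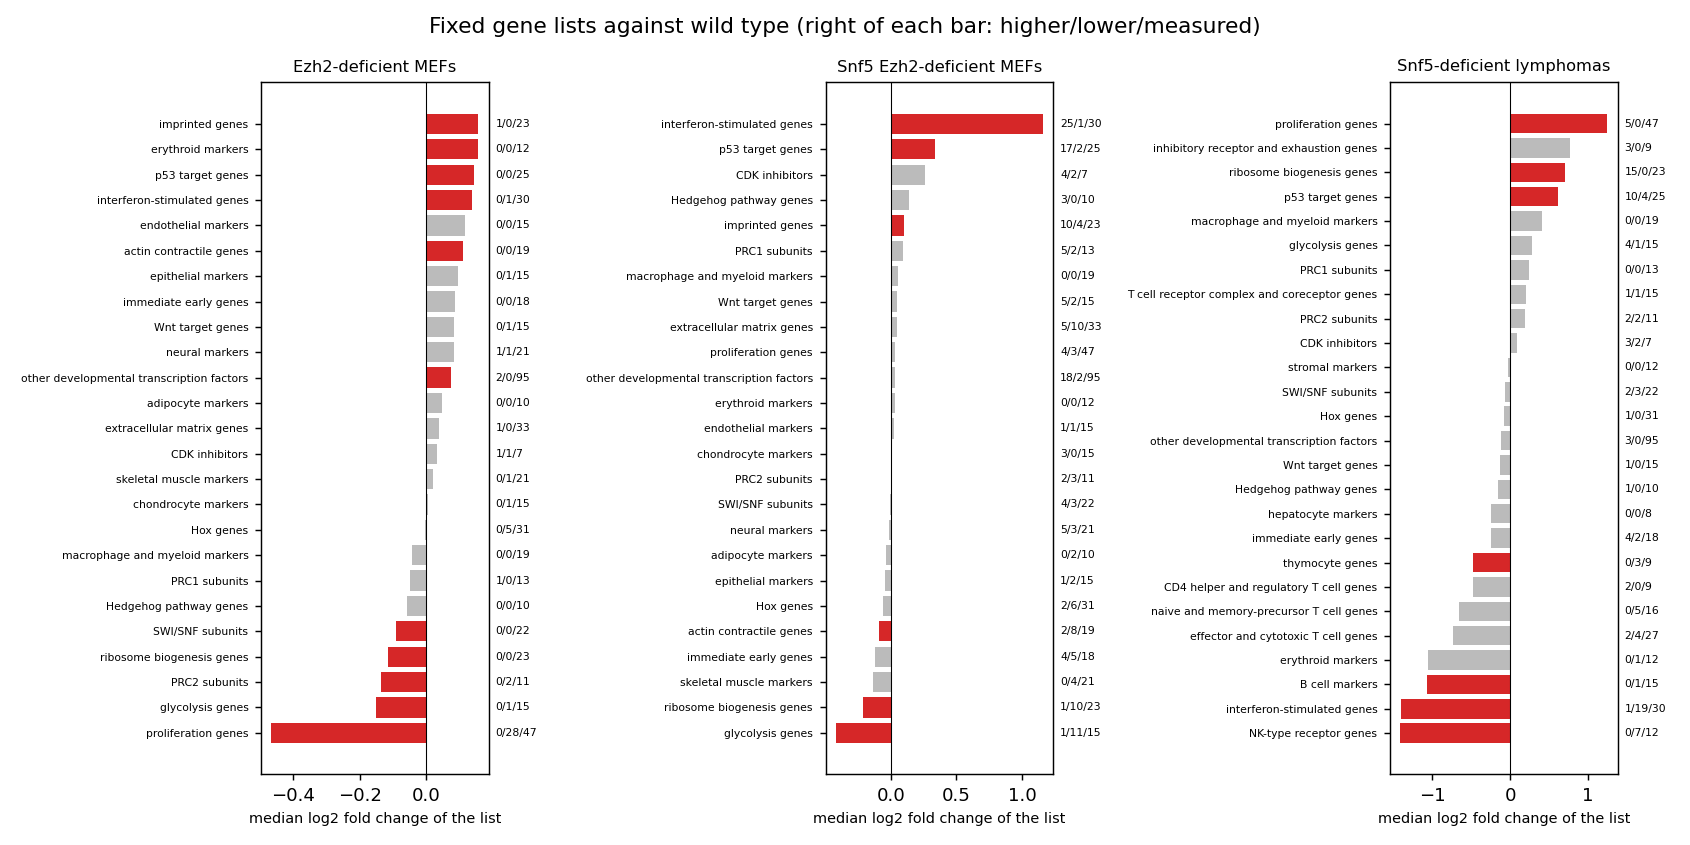
Median log2 fold change of each fixed gene list in the comparison of each MEF line and of the lymphomas with wild type, with members higher, lower and measured at the right of each bar; red bars passed camera with the preset correlation and grey bars did not. The largest median in the Snf5 Ezh2-deficient MEFs was that of interferon-stimulated genes, 1.16.

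The difference between both MEF effects was tested directly and asked what the added loss of Snf5 changes in MEFs without Ezh2. Proliferation genes, lower in the Ezh2-deficient MEFs, were higher in the Snf5 Ezh2-deficient MEFs than in the Ezh2-deficient MEFs, with 39 of 47 higher and 0 lower (median 0.52, adjusted p = 4.4e-15). Interferon-stimulated genes had 21 of 30 higher and 0 lower (0.90, adjusted p = 2.59e-09) and p53 target genes 14 higher and 3 lower of 25 (0.305, adjusted p = 6.62e-05). Actin contractile genes had 0 higher and 10 lower of 19 (-0.23, adjusted p = 0.000294), and skeletal muscle markers 1 higher and 6 lower of 21 (-0.14, adjusted p = 0.0298). Each of these 5 calls was lost at adjusted p = 0.492 with an estimated correlation. Adjusted over the list alone the counts higher and lower were 41 and 0, 22 and 2, 14 and 3, 1 and 10, and 1 and 6 in the same order. The largest differences were those of Agtr2 (4.145), Abi3bp (4.09), Penk (4.00), Ifit1 (3.60) and Cxcl10 (3.57) upward and Prkg2 (-2.56), Tmem87a (-2.53), Smarcb1 (-2.32), Xist (-2.24, adjusted p = 0.0271) and Tinagl1 (-2.175) downward. The Ezh2 probe set was 0.52 higher in the Snf5 Ezh2-deficient than in the Ezh2-deficient MEFs (adjusted p = 0.00812), but not called with the Eif2s3y level as a covariate (0.405, adjusted p = 0.15). In all 3704 genes differed, 2022 upward and 1682 downward, 288 of them at least 2-fold. The count was 1869 with that covariate and 1968 with the 12 arrays of the design, both chosen after the values were seen. With the covariate 26 proliferation genes (median 0.583) and 16 interferon-stimulated genes (1.048) were higher, and the 5 lists kept their calls. The other 21 lists did not pass (adjusted p = 0.0572 to adjusted p = 0.798), and signs differed for the developmental transcription factor, imprinted, Wnt and chondrocyte lists. The muscle list was not called without Ezh2-deficient array 1 (adjusted p = 0.0588) or array 2 (adjusted p = 0.0587), and Xist was not called without Ezh2-deficient array 2 (adjusted p = 0.0839) or 3 (adjusted p = 0.0896) or any of the 3 Snf5 Ezh2-deficient arrays (adjusted p = 0.0635 to adjusted p = 0.0716). Because both effects were taken against the same controls, this comparison was in effect one of the Snf5 Ezh2-deficient with the Ezh2-deficient arrays, and the sets differed in their RMA run. Sex-linked genes differed as well, with 3 higher and 1 lower of 4 (median 1.19). Ezh2-deficient arrays 2 and 3 had the high Xist and low Eif2s3y given above. The fall of Xist goes with that pattern, and the added loss of Snf5 cannot be told apart from sex here.

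The comparison of Snf5-deficient lymphomas with wild-type CD8+ T cells asked which programs differ in tumours that lack Snf5. Gcg, the gene for the precursor of glucagon, had the largest rise of the named genes, 154-fold, from log2 5.86 ± 2.11 (SD, n = 6) to 13.1 ± 0.578 (n = 5; adjusted p = 0.000563). Trat1, an adaptor of the T cell receptor complex, fell 108-fold (10.4 ± 0.587 to 3.68 ± 1.02; adjusted p = 1.44e-05). All 5 lymphoma values of Trat1 lay in the lowest 25% of their arrays, near the floor, where a fold is only that of the RMA values. The chromatin organiser gene Satb1 fell 73.0-fold (adjusted p = 0.000204). In that lowest range lay 2 of 5 lymphoma values of Satb1, 3 of 6 wild-type values of Gcg and of Cdkn2a, and all 5 lymphoma values of Fgf13, Rag2 and Hba-a1. All 6 wild-type values of Hba-a1 lay there too. That range held at least 1 array of 38 of the 82 named genes. The cell cycle inhibitor genes Cdkn2a and Cdkn1a rose 24.6-fold (adjusted p = 0.00151) and 14.4-fold (adjusted p = 0.00311), while ribosome biogenesis genes had 15 of 23 higher and 0 lower. Interferon-stimulated genes were lower, with 19 of 30 down and 1 up. In all, 2088 of 12393 genes changed, 1132 higher and 956 lower, and 1330 changed at least 2-fold, 690 higher and 640 lower.

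Other large rises in the lymphomas were those of the G protein subunit gene Gnai1 (log2 fold change 6.20, SE 1.35), the myelin protein gene Pmp22 (6.00), the glutathione transferase gene Gstt3 (5.93), the adhesion gene Nectin3 (5.61), Ccn4 (5.49), the caveolae gene Cavin1 (5.43) and the phosphatase gene Dusp14 (5.34). Other large falls were those of Klrd1, a receptor subunit of NK and memory T cells (-6.45, SE 0.772), the Notch regulator gene Dtx1 (-6.21), the T cell surface gene Cd7 (-5.85), Nsg2 (-5.63), Fgf13 (-5.55) and the interferon-inducible gene Ifi209 (-5.33). The groups did not overlap in 1420 of the 2088 called genes, and in 12.8% of all genes. The interferon list held Ifit3 (-4.86, SE 0.285), Mx1 (-4.28), Usp18 (-4.20) and Ifit1 (-4.04). Genes of NK-type receptors had 0 of 12 higher and 7 lower, with Klrc1 at -4.07 and Klrk1 at -3.38. Among effector genes Eomes, a transcription factor of memory and effector cells, fell (-4.41) and Il2ra, an interleukin receptor chain, rose (3.825), with 2 of 27 higher and 4 lower. Naive T cell genes had 0 of 16 higher and 5 lower, such as Igfbp4 (-3.63) and Actn1 (-3.52). Inhibitory receptor genes had 3 of 9 higher, with Nr4a2 at 3.35, Ctla4 at 2.51 and Cd160 at 1.315. Genes of CD4 helper and regulatory cells had 2 of 9 higher, Tnfrsf4 (3.40) and Ikzf2 (1.89), and the receptor complex list had Cd28 higher (0.60) and Cd2 lower (-4.05) among 15. Thymocyte genes had 3 of 9 lower, Dntt (-2.54), Cd1d1 (-1.31) and Rag2 (-0.76). Among p53 target genes 10 of 25 rose, such as Phlda3 (2.52), and 4 fell, such as Gadd45a (-2.32). Of 7 CDK inhibitor genes 3 rose and 2 fell, with Cdkn1b at -1.17. Within PRC2, Phf19 rose by 2.20 with Ezh2, and Phf1 (-2.05) and Jarid2 (-0.94) fell. Among developmental transcription factors 3 of 95 rose, Lhx9 (3.91), Foxf2 (3.30) and Lhx2 (1.195). Their wild-type values lay in the lowest 25% on 5, 4 and 5 of 6 arrays. Those of Gstt3, Nectin3 and Ccn4 did so on 4 of 6, and the lymphoma values of Eomes on 4 of 5.

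Camera placed ribosome biogenesis genes (median 0.71, adjusted p = 3.99e-09; 16 higher adjusted over the list alone; adjusted p = 0.159 with an estimated correlation) and proliferation genes (5 of 47 higher and 0 adjusted over the list alone; median 1.25, adjusted p = 4.14e-09; adjusted p = 0.729 with an estimated correlation) higher. It placed interferon-stimulated genes lower (-1.40, adjusted p = 1.58e-08; 1 higher and 19 lower adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). It did the same with NK-type receptor genes (-1.41, adjusted p = 7.31e-05; 8 lower adjusted over the list alone) and thymocyte genes (-0.475, adjusted p = 0.0376; 4 lower adjusted over the list alone), each at adjusted p = 0.166 with an estimated correlation. Passing with less margin were p53 target genes (0.61, adjusted p = 0.0376; 12 higher and 6 lower adjusted over the list alone) on the higher side and B cell markers (1 of 15 lower, Cd79b at -4.01, and 1 adjusted over the list alone; median -1.07, adjusted p = 0.0424) on the lower side, each at adjusted p = 0.729 with an estimated correlation. The other 20 lists did not pass (adjusted p = 0.0656 to adjusted p = 0.946), with effector genes at 2 higher and 6 lower, naive genes at 1 and 5 and inhibitory receptor genes at 4 and 2 adjusted over the list alone. Macrophage and myeloid markers had 0 of 19 past the test (median 0.405), erythroid markers 1 of 12 lower (Hba-a1 at -0.56), and stromal and hepatocyte markers 0 of 12 and 0 of 8. Signs differed for the Hox, developmental transcription factor, immediate early, Wnt, receptor complex, stromal and CD4 lists.

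The wild-type arrays were unlike one another. The receptor complex list mean was 10.97, 12.56, 12.76, 12.74, 12.33 and 10.76 in wild-type arrays 1 to 6, where arrays 1 and 6 had B cell list means of 11.2 and 11.1 against 7.43 to 8.92 in the others, and myeloid list means of 11.997 and 11.913 against 6.48 to 8.16. In the lymphomas the B cell mean was 7.52 to 8.04 and the myeloid mean 10.4, 7.94, 9.70, 9.32 and 10.4. The proliferation list mean was 11.38, 10.65, 8.735, 8.96, 10.78 and 11.61 in the wild-type arrays and 11.5 to 11.7 in the lymphomas. With wild-type arrays 2 to 5 alone, a setting chosen after the values were seen, 34 proliferation genes were higher (median 1.93) and 3273 genes changed, the myeloid list had 11 of 19 higher (median 2.125, adjusted p = 2.01e-05), and the B cell and thymocyte lists were not called (adjusted p = 0.386 and adjusted p = 0.0796). In that setting the naive T cell list, with 7 lower (median -1.318, adjusted p = 0.00104), and the glycolysis list, with 7 higher and 1 lower (0.708, adjusted p = 0.00359), were called. These calls used the preset correlation only, while the correlation estimated in the main fit was 0.517 for the naive and 0.191 for the glycolysis list. The interferon list, with means of 10.2 to 10.8 in the wild-type arrays and 8.74 to 9.54 in the lymphomas, was not called with the B cell and myeloid means as covariates (-0.79, adjusted p = 0.0639), a setting in which 383 genes changed and Smarcb1 stood at -2.13 (adjusted p = 0.614). There the ribosome biogenesis list lost its call too, with 0 members higher (median 0.311, adjusted p = 0.0781), as did the p53 (adjusted p = 0.441) and thymocyte lists (adjusted p = 0.559). The B cell list (adjusted p = 0.983) was adjusted for its own mean in that setting, so the loss of its call was fixed by construction. The naive (-2.093, adjusted p = 0.00207), effector (-2.421, adjusted p = 0.000362) and immediate early lists (-1.911, adjusted p = 0.000931) gained calls, each on the lower side and with the preset correlation only. The correlations estimated for them in the main fit were 0.517, 0.2 and 0.332. With the Eif2s3y level as a covariate the p53 (adjusted p = 0.112), thymocyte (adjusted p = 0.0506) and B cell lists (adjusted p = 0.409) were not called. The myeloid (1.557) and effector lists (-1.159; adjusted p = 0.0149 for each), the naive list (-0.856, adjusted p = 0.0402) and the glycolysis list (0.614, adjusted p = 0.0156) were called there. With the Gapdh gap described next as a covariate the p53 (adjusted p = 0.184), thymocyte (adjusted p = 0.0533) and B cell calls (adjusted p = 0.121) ended too. The gap between 3' and 5' control probe sets of Gapdh, which widens when RNA is degraded, was 0.80, 0.79, 0.88, 1.71, 3.96 and 2.86 in the wild-type arrays and 0.70 to 1.05 in the lymphomas. Xist read 12.85 to 13.51 in all 6 wild-type arrays and 13.19, 5.44, 5.15, 4.85 and 12.25 in the lymphomas (adjusted p = 0.0483), where Eif2s3y read 3.45, 11.81, 11.93, 12.55 and 3.32 against 3.20, 3.46, 9.84, 6.11, 3.91 and 3.22 in the wild-type arrays.

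Without 1 array at a time the number of changed genes was 1408 to 2303 in the lymphoma comparison. The 5 called proliferation genes became 11, 2, 1, 2, 1 and 17 without wild-type arrays 1 to 6 and 1, 3, 0, 0 and 0 without lymphoma arrays 1 to 5. The 7 lower NK-type receptor genes became 4 without lymphoma array 3 or 4, and the 15 higher ribosome biogenesis genes became 9 without lymphoma array 4 and 8 without lymphoma array 5. The p53 list was not called without wild-type array 5 (adjusted p = 0.0882), lymphoma array 2 (adjusted p = 0.0608) or lymphoma array 3 (adjusted p = 0.0537), and the thymocyte list was not called without wild-type array 6 (adjusted p = 0.0554) or lymphoma array 2 (adjusted p = 0.0538). The B cell list lost its call without wild-type arrays 1 (adjusted p = 0.159), 5 (adjusted p = 0.052) and 6 (adjusted p = 0.144) and lymphoma arrays 2 (adjusted p = 0.0538), 3 (adjusted p = 0.0537) and 4 (adjusted p = 0.0604). The naive T cell list gained one without wild-type arrays 1 (adjusted p = 0.0356) and 6 (adjusted p = 0.0171) and lymphoma array 1 (adjusted p = 0.0326). Of the 76 called genes of the named set, 50 kept their call without each array, among them Gcg, Trat1, Satb1, Cdkn2a, Cdkn1a, Ifit3, Eomes and Il2ra. The others included Klrk1, not called without lymphoma array 3 (adjusted p = 0.059) or 4 (adjusted p = 0.0607), Jarid2, not called without lymphoma array 5 (adjusted p = 0.0528), and Rag2, not called without lymphoma array 3 (adjusted p = 0.0507). The calls of Ctla4, Cd160, Cd28, Ikzf2, Lhx2, Hba-a1 and Xist ended without any of 5 or more of the 11 arrays (adjusted p = 0.0525 to adjusted p = 0.116).

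**Figure D3:**
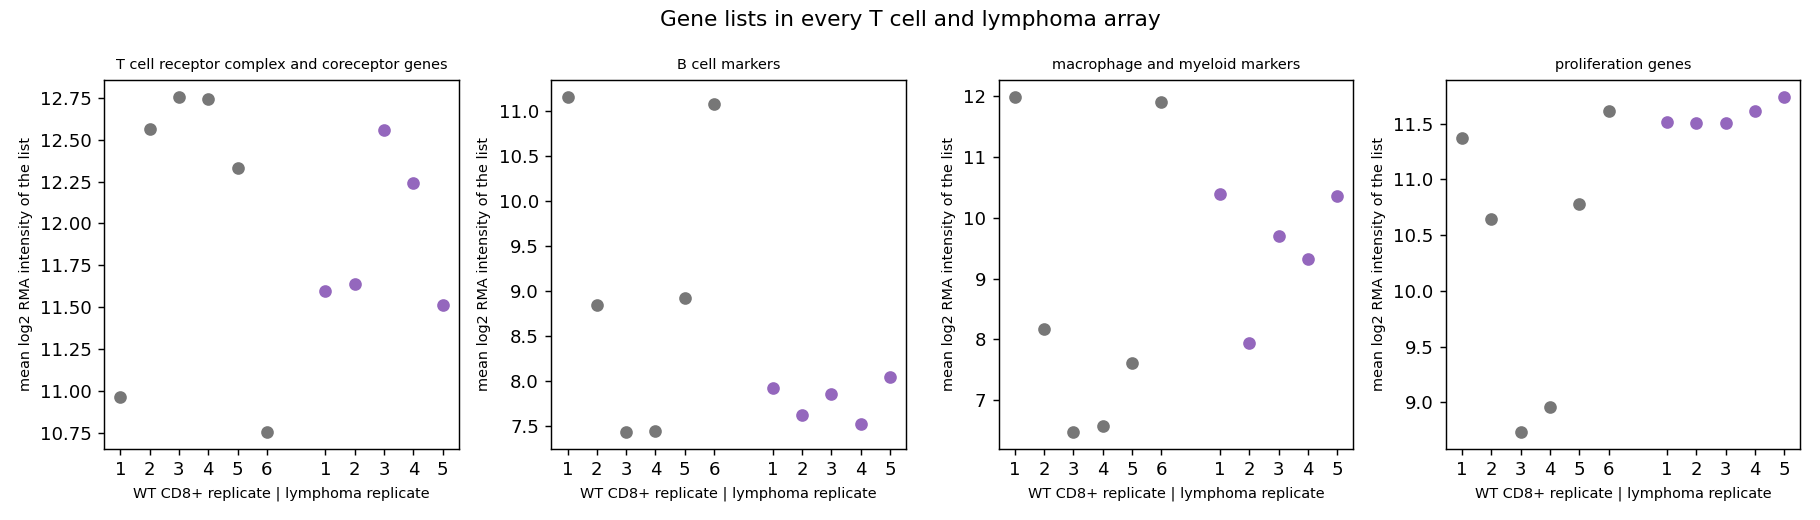
Mean log2 intensity of the T cell receptor, B cell, myeloid and proliferation lists on each of the 6 wild-type and 5 lymphoma arrays, with 1 point per array. Wild-type arrays 1 and 6 had receptor complex means of 10.97 and 10.76 and myeloid means of 11.997 and 11.913.

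The overlap of the comparisons asked whether loss of Ezh2, combined loss and lymphoma change the same genes. Both MEF lines shared 52 genes that rose (16.6 expected from the numbers called; Fisher exact p = 3.45e-15) and 115 that fell (43.9 expected; Fisher exact p = 1.67e-24) among 12393 genes, with Wdfy1, Hebp1, Pop4 and Efcab7 among the shared shifts; 10 and 27 genes went opposite ways (18.1 and 40.3 expected). Across genes the log2 changes had r = 0.282 and rho = 0.302. All 3 controls were common to both comparisons, while the expected numbers take the comparisons as independent. In 100 simulations without any effect the common controls alone gave r = 0.499 (0.457 to 0.529). The same sign was found for 66.6% of genes there, against 61.1% observed, and the covariance was 0.00443 against 0.0202 observed. Changes particular to 1 line widen the spread of the observed values and lower r and the same-sign share. Neither can therefore be set against a simulation without effects. The covariance is not scaled by that spread, and its observed value lay above the simulated range (0.00397 to 0.00482). Calls in the same direction numbered 0.02 on average, against 167 observed. Without an effect almost no gene can be called, so that count does not tell how many of the 167 the common controls gave. Without wild-type arrays 1, 2 and 3 the 167 became 109, 52 and 61, and without Ezh2-deficient arrays 1 and 3 they became 57 and 98. Ezh2-deficient MEFs and lymphomas shared 9 genes that rose (11.5 expected) and 9 that fell (23.6 expected; Fisher exact p = 0.000682), while 61 genes fell in the MEFs and rose in the lymphomas (28.0 expected; Fisher exact p = 4.08e-09). The 18 genes of the same direction became 3 and 1 without wild-type MEF arrays 2 and 3, 3 and 8 without Ezh2-deficient arrays 1 and 3 and 11 without lymphoma array 4. The 61 genes rest on the same Ezh2 calls, whose number fell without single arrays as given above. Snf5 Ezh2-deficient MEFs and lymphomas shared 217 genes that rose (149.1 expected; Fisher exact p = 2.31e-09) and 155 that fell (137.2 expected; Fisher exact p = 0.0927), yet 186 and 212 genes went opposite ways (125.9 and 162.4 expected), and r across genes was 0.004. Genes are not independent replicates, so these p-values describe tables of genes.

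As a set, the 1132 genes that rose in the lymphomas had a median log2 change of -0.05 in the Ezh2-deficient MEFs, where 39.2% lay above 0 against 51.0% of all genes (9 called higher and 61 called lower; camera p = 0.00199; p = 0.11 with an estimated correlation). The same set had a median of 0.007 in the Snf5 Ezh2-deficient MEFs, with 217 higher and 212 lower (camera p = 0.515 with the preset correlation). In the difference between both MEF effects its median was 0.037, with 297 higher and 143 lower and 54.5% above 0 against 44.9% of all genes (camera p = 0.00751; p = 0.156 with an estimated correlation). The 956 genes that fell in the lymphomas had medians of 0.03 and 0.02 in the Ezh2-deficient and the Snf5 Ezh2-deficient MEFs (camera p = 0.126 and p = 0.253 with the preset correlation).

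**Figure D4:**
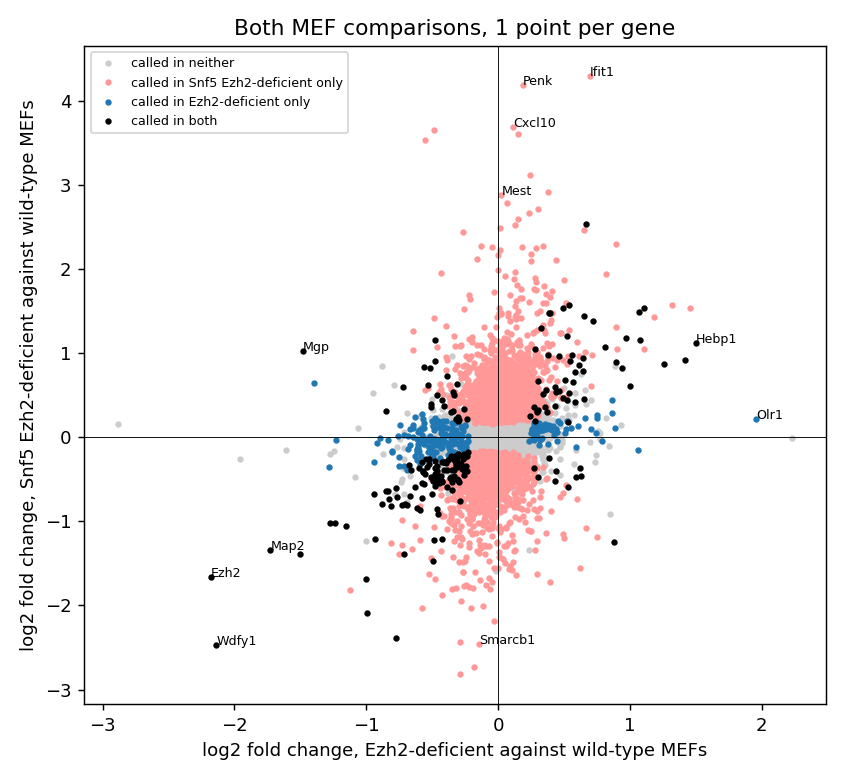
Log2 fold change of each gene in the Ezh2-deficient MEFs (horizontal) and the Snf5 Ezh2-deficient MEFs (vertical), both against the same wild-type MEFs, coloured by the comparison in which it was called. Of the genes called in both, 52 were higher and 115 lower in both lines.

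The comparison of both wild-type MEF sets was planned as a check for a difference between the experiments, but it compared 2 RMA summaries of the same 3 hybridisations. Even so, 717 genes passed, 138 higher and 579 lower in the second set, 3 of them at least 2-fold. The fit took the 6 summaries as separate arrays although they repeat the same hybridisations. The count is therefore no measure of how many genes the summaries shift. The median difference over all genes was -0.068, on the side of the 579 lower genes. The largest differences were those of Ldb2 (1.05), Tek (1.01), Rbbp9 (0.95), Zfp395 (0.82) and Kank3 (0.73) upward and Bace1 (-1.09), Adgra3 (-0.82), Oxtr (-0.79), Sema5b (-0.79) and Smcp (-0.775) downward. They are differences of summarisation and not of the cells. The count became 319 to 388 without 1 of the 6 summaries in turn.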

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

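The tests of the 3 patterns weighed here, and the counts of other splits, were chosen only after the results were seen.

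Proliferation genes were lower in the Ezh2-deficient MEFs (median -0.465), and their effect differed between both MEF lines by 0.52. With an estimated correlation these calls were lost (adjusted p = 0.336 and adjusted p = 0.492). Normalisation between arrays stays undecided. Under repeated quantile normalisation or median centring the median was still -0.448 at its nearest to 0. The deposited values were quantile-normalised already, so this test could hardly have come out otherwise. A higher Cdkn2a acting alone cannot be told apart: the list median was 0.032 in the Snf5 Ezh2-deficient MEFs, where Cdkn2a was also called, but it rose less there (0.88 against 1.256), its call ended without 3 of the 6 arrays, and the added loss of Snf5 was not separated from it. With the Eif2s3y level as a covariate, which took the sex-linked list from -1.15 to 0.03, the proliferation median was -0.52 (adjusted p = 5.05e-27 by camera) with 4 members called. That fit rests on the 1 Ezh2-deficient array with the male pattern of the wild-type arrays, whose list mean lay at -0.408 from the lowest of them. As 1 array decides nothing by itself, the sex of the embryos cannot be told apart from the genotype. Reduced division after loss of Ezh2 may be the biological explanation, and it stays a hypothesis, with Cdkn2a, sex and normalisation left open.

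Interferon-stimulated genes were higher in the Snf5 Ezh2-deficient MEFs, and their effect differed between both MEF lines by 0.904. With an estimated correlation these calls were lost (adjusted p = 0.607 and adjusted p = 0.492). Macrophages in the cultures are argued against by a myeloid list median of 0.058, and a single array by 22 members still called higher in the least favourable left-out fit. Normalisation between arrays was not decided by a lowest list median of 1.149, since repeating it on values already normalised could hardly move the list. The limits of these tests were set after the values were seen, so they exclude nothing. An interferon response that follows combined loss is a candidate explanation, found and tested on the same data. MEFs that lack Snf5 alone were not measured, so loss of Snf5 by itself cannot be told apart from combined loss. Infection of the cultures, or their separate handling, was not tested.

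Wild-type T cell arrays 1 and 6 were low in T cell receptor genes, with Cd8b1 at 9.35 and 8.07 against 12.53 to 13.61 in the other 4. Degraded RNA is argued against in array 1, whose Gapdh gap lay at -3.163 from the highest of arrays 2 to 5 and below that of 3 of them. It cannot be told apart in array 6, whose gap of 2.86 was wider than in all of these but array 5, from which it lay at -1.1. A swap of labels with lymphomas is argued against by Smarcb1, at least 2.45 above every lymphoma. Other blood cells in the purified cells may be the source: B cell and myeloid list means of both arrays lay at least 2.162 and 3.75 above those of the other wild-type arrays, with Cd79a at 12.06 and 11.69 and Lyz2 at 14.22 and 14.2. Of the B cell list, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 are also made by macrophages, and Fcgr3 is in both the NK and the myeloid list. The purification named in the labels would be meant to remove such cells, and no biological explanation was tested, since the design gives none.

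Other splits of the arrays were counted for each comparison. The 10 splits of 3 arrays against 3 are too few for a share under 0.05, with 432, 3410, 3704 and 717 genes in the real splits of the Ezh2, Snf5 Ezh2, difference and control set comparisons and 0 in the highest other split of each, so that 1 split reached the real count. For the lymphomas 100 of 462 possible splits were drawn. Only 1 of them, the real one, gave as many as 2088 genes, and the highest other gave 283. Random groupings of these arrays thus rarely gave such a count. The splits do not tell what separates the groups, whose arrays also differed in blood cell markers, Gapdh gap and Xist.

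The effects of 3 further lists differed between both MEF lines by a direct test: p53 target genes by 0.305, actin contractile genes by -0.228 and skeletal muscle markers by -0.136. Each of these calls was lost with an estimated correlation (adjusted p = 0.492), and that of the muscle list also without Ezh2-deficient array 1 (adjusted p = 0.0588) or 2 (adjusted p = 0.0587). The Gapdh control gap was wider than in any lymphoma in wild-type T cell arrays 4 (1.71), 5 (3.96) and 6 (2.86).

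Single values lay far from the rest of their group in 10 of 218 groups examined, where chance gives 10.9. The interferon list mean of wild-type T cell array 4 was 10.2, below the others. Among genes in the wild-type arrays, Gzmk read 11.9 and Ifi209 read 8.54 in array 3, Ifit1 read 11.56 and Ikzf2 read 4.55 in array 2, Lhx9 read 5.97 in array 4 and Nop16 read 9.43 in array 5. Among the lymphomas, Actn1 read 7.29 in array 2, Nop16 read 10.34 in array 1 and Tk1 read 12.61 in array 4.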

How the results depend on the processing

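The tests with the 12 arrays of the design, with the Eif2s3y level, with fewer wild-type T cell arrays, with B cell and myeloid means, with the Gapdh gap and with lists without the deleted genes were chosen only after the results were seen. Of these results, directions of called values held under every alternative run except with B cell and myeloid means as covariates, and the number of arrays and the spread between them limit all of them. Except where the construction is named, the cause was not tested.

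With array weights the counts were 907 in the Ezh2, 3227 in the lymphoma and 1365 in the control set comparison, and 326, 72 and 559 genes were shared in the same direction by Ezh2 and Snf5 Ezh2 MEFs, Ezh2 MEFs and lymphomas, and Snf5 Ezh2 MEFs and lymphomas. A 2-fold minimum, which removes smaller changes by construction, left 20, 316, 1330, 288 and 3 genes in the Ezh2, Snf5 Ezh2, lymphoma, difference and control set comparisons and 12, 1 and 31 shared genes. With all arrays in one fit, where the wider spread of the T cell arrays enters the variance of the MEFs, the counts were 1, 219, 4087 and 192 in the first 4 of these, with 1, 0 and 30 shared genes. In that fit Ezh2 stayed at -2.18 in the Ezh2-deficient MEFs (adjusted p = 0.0797) and at 0.52 in the difference (adjusted p = 1), and Smarcb1 at -2.46 in the Snf5 Ezh2-deficient MEFs (adjusted p = 0.0698) and at -2.32 in the difference (adjusted p = 0.103). With only the 2 groups compared, fewer degrees of freedom left 258 Ezh2 genes and 102 and 11 shared genes. The mean of a gene's probe sets gave 30 genes shared by Ezh2 MEFs and lymphomas. The control set comparison gave 453 genes with arrays centred on their median and 57 without the dimmest probe sets.

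With the replicate number as a replicate block the Ezh2 count was 213, with 100 and 10 shared genes. The arrays share only a number per the labels, and not every same-number correlation of residuals was over 0.1, so they were not taken as pairs. The correlations were -0.03 to 0.15 between wild-type and Ezh2-deficient MEFs, -0.04 to 0.03 for Snf5 Ezh2-deficient MEFs and 0.08 to 0.31 between T cells and lymphomas. Best with their own number were 2 of 3, 1 of 3 and 3 of 5 pairs, so a pairing of the T cell arrays is not excluded. The block spends degrees of freedom, which by itself can end calls.

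With the 12 arrays of the design, which count the controls again, the Ezh2 count was 851, the difference 1968 and the shared genes 318 and 42; 430 of the 432 Ezh2 genes kept their call. With the Eif2s3y level the Ezh2 count was 73, the difference 1869 and the shared genes 34 and 3, and Ezh2 in the difference was 0.405 (adjusted p = 0.15). With wild-type T cell arrays 2 to 5 or 2 to 4 the lymphoma count was 3273 or 3303, with 35 genes shared with Ezh2 MEFs in each. With B cell and myeloid means as covariates the lymphoma count was 383, with 6 and 74 shared genes, and Smarcb1 stood at -2.13 (adjusted p = 0.614). There the immediate early list, not called before, was called on the lower side (median -1.911 against -0.248). The direction turned for the B cell list (0.169), Smarcd1 (-0.58), Aldoc (-0.32), Nr4a1 (-0.49), Gzmc (-2.42), Cd160 (-0.58), Cd28 (-0.46) and Rag2 (0.13). For the B cell list the turn says nothing, since its own mean was a covariate.

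Genes called higher in the lymphomas had a median of -0.049 in the Ezh2-deficient MEFs (p = 0.11 with an estimated correlation). Those called lower passed after quantile normalisation (0.033; p = 0.0195 with the preset correlation) and without the dimmest probe sets (-0.001; p = 0.00744 with the preset correlation). Leaving out 1 array at a time gave 87 to 443 genes in the Ezh2, 2690 to 3086 in the Snf5 Ezh2, 2842 to 3501 in the difference and 319 to 388 in the control set comparison, 52 to 169 genes shared by both MEF lines and 1 to 22 shared by Ezh2 MEFs and lymphomas. With an estimated correlation all 29 list calls were lost. Among named genes, calls were lost for 108 with all arrays in one fit, 40 with the Eif2s3y level and 30 with the replicate block, each over several comparisons. The B cell and myeloid means and the Gapdh gap were used in the lymphoma comparison alone, where 76 of these genes were called. There 52 and 19 calls were lost, and 7 further genes turned direction with the B cell and myeloid means. These counts rest on different sets of genes and give no ranking of the settings.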

Other observations

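The tests of lymphoma RNA in wild-type T cell array 4 were chosen only after the result was seen, while those of genes near Ezh2 and Smarcb1 were written before.

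Single genes of further kinds changed in the Snf5 Ezh2-deficient MEFs, while the epithelial, adipocyte, endothelial and immediate early lists did not pass camera (adjusted p = 0.439 to adjusted p = 0.937). Ccn2, a growth factor induced by tension, and the integrin gene Itga5 were lower (log2 fold change -1.36 and -1.24), while the smooth muscle genes Actg2 and Myh11 were higher (0.95 and 0.975). The epithelial keratin genes Krt7 and Krt18 fell (-1.69 and -1.20, the latter to values near the floor), the lipid genes Fabp4 and Lpl fell (-1.44 and -0.73), and the endothelial receptor gene Tek rose by 1.46, although the same gene differed by 1.01 between both RMA summaries of the controls. Among immediate early genes Egr2, near the floor in the wild-type MEFs, and Klf4 were higher (0.87 and 0.69) and Ier2 and Dusp1 lower (-0.85 and -0.67). Myh11 lost its call without any of the 6 arrays compared (adjusted p = 0.0714 to adjusted p = 0.146).

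In the lymphomas Ccn1, a matrix protein of wound repair, and Atf3, a stress-induced factor, were higher (3.985 and 2.15), and the phosphatase gene Dusp2 was lower (-3.21). The glycolysis genes Tpi1 and Pfkl were higher (1.53 and 0.72) and the kinase gene Pdk1 lower (-1.83), and of 22 SWI/SNF genes 2 were higher, Smarcc1 (0.97) and Smarcd1 (0.71), and 3 lower, among them Smarcb1 itself and Smarca2 (-1.11). Of the ribosome biogenesis list, Nop16 (1.02), Wdr12 (0.93) and Srm (0.92), a polyamine synthesis gene, were higher. The calls of Atf3, Pfkl and Smarcc1 ended without any of 7 of the 11 arrays, that of Smarcd1 without any of 9, that of Pdk1 without lymphoma array 4 (adjusted p = 0.055) or 5 (adjusted p = 0.058), and that of Dusp2 without lymphoma array 3 (adjusted p = 0.0512). The erythroid list mean was 7.41, 8.18, 5.43, 5.13 and 7.53 in lymphoma arrays 1 to 5, where Smarcb1 read 8.30, 8.49, 5.81, 5.64 and 8.67.

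A hypothesis for the large shifts shared by both MEF lines, such as Wdfy1 (-2.14 and -2.47), Glo1 (-1.155 and -1.06), Alad (-0.83 and -0.645), Efcab7 (-1.28 and -1.02), Pop4 (1.08 and 1.15) and Hebp1 (1.5 and 1.12), is that the mutant and wild-type lines may differ in strain background. Nnt, a gene known to vary between strains, was not shared: it fell in the Ezh2-deficient MEFs (-0.919, adjusted p = 0.00012) and stood at -0.069 in the Snf5 Ezh2-deficient MEFs (adjusted p = 0.527). Of the 100 measured genes nearest to Ezh2, 4 were called in the Ezh2-deficient MEFs, against 3.48% of the rest (Fisher exact p = 0.78), and of the 100 nearest to Smarcb1, 32 were called in the difference, against 29.9% (Fisher exact p = 0.661). Flanking DNA of another strain cannot be told apart from its absence by this test, because such a stretch may hold few genes that differ between strains. The strains are not given in the sources used here. Both lines also lack Ezh2 and were compared with the same controls. Loss of Ezh2 and the common controls therefore cannot be told apart from strain as a source of shared shifts.

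Gcg read 9.49 in wild-type T cell array 4 against 3.73 to 6.81 in the other wild-type arrays and 12.54 to 13.88 in the lymphomas. A hypothesis of lymphoma RNA in that array was tested on the 36 other genes whose lowest lymphoma lay at least 4 above wild-type arrays 2, 3 and 5. Of these, 21 lay further below the lowest lymphoma in array 4 than Gcg lay below the highest (4.39) and 15 did not. Lhx9, called higher in the lymphomas, also stood out upward in that array (5.97 against 3.94 to 4.68 in the other wild-type arrays), and Eif2s3y read 6.11 there. Eif2s3y read higher still in wild-type array 3, where Gcg lay within the 3.73 to 6.81 given above. The source of Gcg in array 4 stays open.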
